A study of Mus musculus with 6 samples.

How the data were processed

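The values came from 6 Affymetrix whole-transcript arrays, each hybridised with biotin-labelled total RNA from mouse CD4+ CD44+ T cells of draining lymph nodes. The labels place the arrays in 3 sorted groups of 2, named by surface Cxcr5 and by a red fluorescent Bcl6 reporter: Cxcr5+Bcl6+, Cxcr5+Bcl6- and Cxcr5-Bcl6-. The series describes the arrays of a group as biological replicates. Whether mice were pooled, and whether cells were handled on the same day, is not given in the sources used here. Nor is it given whether the sorted cells were restimulated before RNA extraction, on which cytokine levels would depend. The mice were males of 8 to 10 weeks immunised with keyhole limpet haemocyanin in complete Freund's adjuvant.

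The deposited values are probe-set levels on the log2 scale, which the authors had normalised across arrays. The labels name GCOS 1.1, RMA and Affymetrix Expression Console without their order or settings, so whether RMA ran at its default settings is unknown. The log2 scale was read from the range of the values. Genome build, detection calls and scanner files are not given in the sources used here, so background correction was not varied and no positions are given. For arrays, the number of arrays limits the precision, and no depth applies.

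Of 35556 rows, 21789 probe sets carried 1 gene symbol, 1621 carried several and 12146 were unnamed here. Symbols came from the platform's annotation table. They were updated through Entrez identifiers for 21698 of the singly named probe sets, and the other 91 kept the symbol of that table. The 23410 named probe sets were tested with limma 3.58.1 in R 4.3.3, using lmFit with group means over all 6 arrays and eBayes at its default settings. The moderated test was two-sided, with Benjamini-Hochberg adjustment over the 23410 probe sets and a threshold of 0.05 on the adjusted p, with no fold threshold. The fit had 3 residual degrees of freedom and a prior of 8.25 degrees of freedom with an SD of 0.0989 (log2). The 3 comparisons share these arrays and are not independent. Counts are of probe sets, whereas lists and rankings used 1 probe set per gene, the one with the highest mean over the 6 arrays, which gave 19938 genes.

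A total of 26 gene lists holding 406 genes, 358 of them measured, were fixed before the data were examined. They were follicular helper, T helper 1, T helper 2, T helper 17, regulatory T cell, naive and central memory T cell, effector differentiation opposed to Bcl6, cell cycle, glycolysis and mTORC1, cholesterol synthesis, type I interferon response, T cell receptor early response, coinhibitory receptors, cytokines, cytokine receptors, chemokine receptors and trafficking, dissociation and stress response, ribosomal proteins and T cell core. Lists for other cells that the sort could hold were B cell, germinal centre B and plasma cell, myeloid and dendritic cell, CD8 T cell, NK and innate-like T cell, stromal and endothelial cell, and erythroid and platelet. Some genes stand in more than 1 list. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 26 lists of a comparison, and again with an estimated correlation and with fry.

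Named genes followed a rule fixed before the data were examined. It took the sort genes Bcl6 and Cxcr5, then per comparison the 10 largest rises and 10 largest falls among probe sets past the threshold whose groups did not overlap, then up to 4 members of each list with the smallest p. Genes without a curated symbol were left out of the ranks. They were 1 fall for Cxcr5+Bcl6+ against Cxcr5-Bcl6-, and 1 rise and 1 fall for Cxcr5+Bcl6+ against Cxcr5+Bcl6-. Any other gene is said to have been chosen after its values were seen. Where a gene has several probe sets, the calls of named genes disagreed for Idi1 in the comparison of Cxcr5+Bcl6- with Cxcr5-Bcl6- and for Fdft1 in the comparison of the Cxcr5+ groups with each other.

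Alternatives were an intensity trend or robust option in eBayes, renewed quantile normalisation, centring each array on its median, filters on dim probe sets at the 25th percentile and the median, all rows, 1 probe set per gene, a fit to the 4 arrays compared, an adjusted p under 0.1, a change of at least 1.5-fold, the replicate number as a term, and leaving out each array in turn. Splitting the 2 control arrays between the comparisons, and leaving Bcl6 and Cxcr5 out of the lists that hold them, were added after seeing the data. The fit was also tested on simulated data with the spread of these arrays and 200 changed probe sets in each of 10 runs. A 2-fold change was recovered in 100% of cases, a 1.5-fold change in 95.7% to 96.6% and a 1.25-fold change in 22.4% to 23.7%. The false share of calls was 6.84% to 7.44%, above the nominal 5%. The data gave 2610 to 8255 calls per comparison, far more than the changed probe sets simulated, so these rates need not hold there. A list shifted 1.5-fold was found in 10 of 10 runs, and 8 to 10 other lists were called over these runs. The simulated noise was independent between genes, so these runs did not test the preset correlation. Some of the other lists can share genes with the shifted one. Groups of 2 were too small for a test of other splits of the arrays or of single arrays far from their group.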

Results

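Gene expression was measured in 3 sorted populations of antigen-experienced (CD44+) CD4+ T cells from the draining lymph nodes of immunised Bcl6 reporter mice, with 2 arrays per population. Cxcr5 is the chemokine receptor that directs lymphocytes to B cell follicles, and Bcl6 is the transcriptional repressor required for follicular helper T cells. The populations carried both markers (Cxcr5+Bcl6+), the receptor alone (Cxcr5+Bcl6-) or neither (Cxcr5-Bcl6-). The title of the series names the question, whether Bcl6 expression marks the follicular helper program in living mice. Arrays of a group correlated across probe sets at r = 0.9966 for Cxcr5+Bcl6+, 0.9970 for Cxcr5-Bcl6- and 0.9985 for Cxcr5+Bcl6-, against 0.9706 to 0.9924 between groups. Probe sets are not independent replicates. The first principal component held 73.9% of the variance and set the Cxcr5+Bcl6+ arrays (-43.4 and -41.1) apart from the Cxcr5-Bcl6- arrays (34.0 and 27.8), with the Cxcr5+Bcl6- arrays between them (11.97 and 10.74). The interquartile range of levels was 2.91 and 3.05 in the Cxcr5+Bcl6+ arrays and 3.15 to 3.32 in the others.

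The sort genes served as a check of the labels and are not findings. Bcl6 (probe set 10438738) averaged 10.31 ± 0.00243 in Cxcr5-Bcl6-, 10.56 ± 0.00685 in Cxcr5+Bcl6- and 11.5 ± 0.0696 in Cxcr5+Bcl6+ cells (log2 level, SD, n = 2 each). It was higher in Cxcr5+Bcl6+ than in Cxcr5-Bcl6- cells by 1.19 and than in Cxcr5+Bcl6- cells by 0.94 (adjusted p = 1.15e-06 and adjusted p = 1.4e-05). The 0.25 between Cxcr5+Bcl6- and Cxcr5-Bcl6- cells did not pass (adjusted p = 0.103), although it did after renewed quantile normalisation (adjusted p = 0.0409). Cxcr5 (probe set 10592888) averaged 7.47 ± 0.191, 9.94 ± 0.0487 and 10.996 ± 0.0254 in the same order. It differed by 3.52 between Cxcr5+Bcl6+ and Cxcr5-Bcl6- cells, by 2.47 between Cxcr5+Bcl6- and Cxcr5-Bcl6- cells and by 1.05 between the Cxcr5+ groups (adjusted p = 1.47e-09, 2.07e-07 and 2.15e-05).

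**Figure D1:**
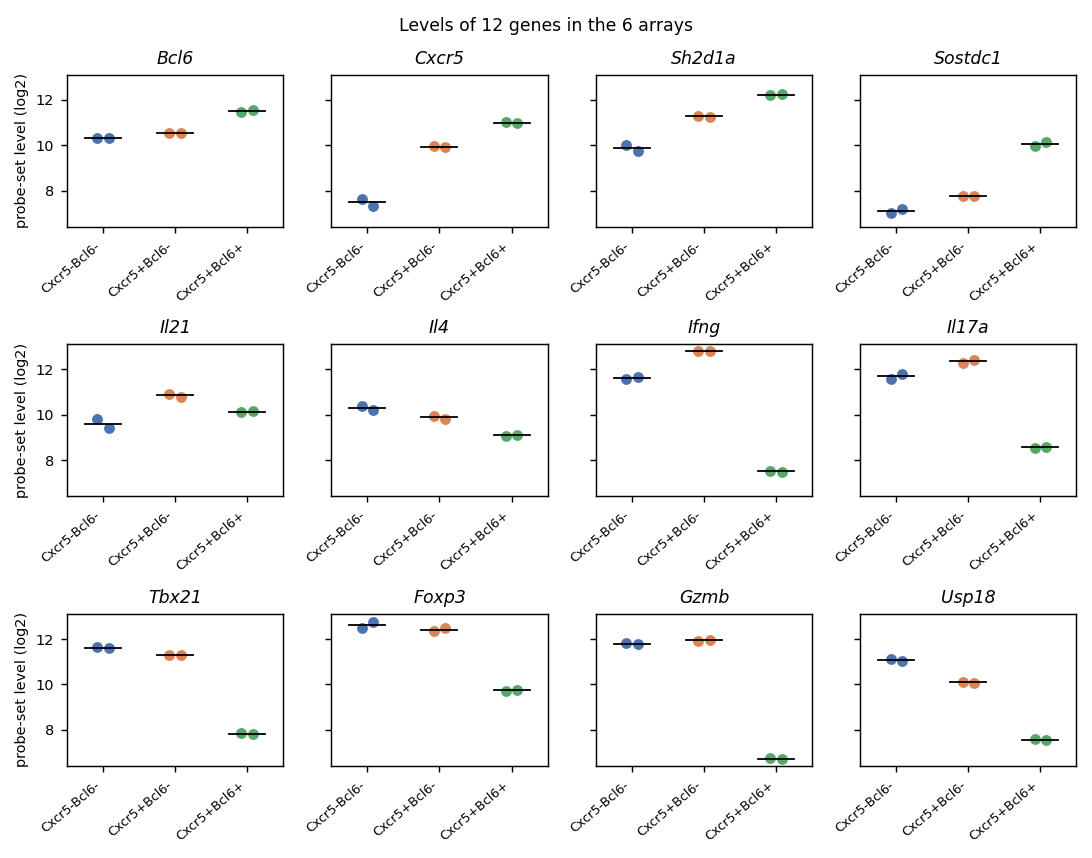
Log2 probe-set level of 12 genes (vertical axis) in the 3 sorted groups (horizontal axis), where dots are the 2 arrays of a group and lines their mean. Ifng stood at 12.81 in Cxcr5+Bcl6-, 11.64 in Cxcr5-Bcl6- and 7.50 in Cxcr5+Bcl6+ cells, whereas Sostdc1 was highest in Cxcr5+Bcl6+ cells at 10.06.

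Compared with Cxcr5-Bcl6- cells, Cxcr5+Bcl6+ cells had lower levels of 10 of 15 T helper 1 genes and 16 of 19 cytokine genes and higher levels of 17 of 29 follicular helper genes. Gzmb (probe set 10420308), which encodes the cytotoxic protease granzyme B, averaged 6.72 ± 0.0126 against 11.8 ± 0.033 (SD, n = 2 each), a 34.0-fold lower level. Ifng (probe set 10366586), the interferon gamma gene, was 17.6-fold lower (7.50 ± 0.00584 against 11.64 ± 0.0514), and Tbx21 (probe set 10390328), which encodes the T helper 1 regulator T-bet, was 14.0-fold lower (7.82 ± 0.0469 against 11.63 ± 0.0164). Dnase1l3 (probe set 10417526), which encodes a secreted DNase, was 13.5-fold higher (11.15 ± 0.0189 against 7.40 ± 0.0822). Sostdc1 (probe set 10395389), which encodes a secreted antagonist of bone morphogenetic protein and Wnt signals, was 7.79-fold higher (10.06 ± 0.1 against 7.10 ± 0.127). The adjusted p of these 5 genes was 5.96e-11, 2.5e-10, 3.28e-10, 4.83e-10 and 3.08e-09.

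The other large rises, as log2 changes, were Padi4 (3.33), which encodes a protein-citrullinating enzyme, Ica1l (2.84), Sccpdh (2.46), Spock2 (2.46), Fcer2a (2.43), Slc9a9 (2.41) and Cdc25b (2.41), a cell cycle phosphatase. The other large falls were the signalling suppressor Socs2 (-4.71), the cytokine Il3 (-4.53), the chemokines Ccl3 (-4.24) and Ccl22 (-3.98), the interferon-induced GTPase gene Iigp1 (-4.16), the macrophage perforin gene Mpeg1 (-3.62) and Usp18 (-3.50), a brake on type I interferon signalling. Il3 stood at 5.38 in Cxcr5+Bcl6+ cells, under the median level of 5.80 of the olfactory, vomeronasal and trace-amine receptor genes, so its fall is a lower bound. Each had an adjusted p of 4.67e-08 or less.

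Follicular helper genes rose as a list (median log2 change 0.60, adjusted p = 7.31e-07, and adjusted p = 0.149 with an estimated correlation). Of 29 measured members, 17 rose, 4 fell and 8 did not pass. The list holds both sort genes, and without them the median was 0.54 (adjusted p = 1.54e-05, and adjusted p = 0.161 with an estimated correlation). Besides Cxcr5 and Sostdc1, the leading rises were Sh2d1a (2.35), which encodes the signalling adaptor SAP, and the nuclear factor gene Tox2 (1.99). The 4 that fell, named after their values were seen, were Il4 (-1.23), Rgs16 (-0.77), Cd40lg (-0.77) and Cd200 (-0.38). They encode the helper cytokine interleukin 4, a G protein regulator, the CD40 ligand that activates B cells, and an inhibitory surface ligand.

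Lists of the other lineages fell. T helper 1 genes (median -1.43, adjusted p = 3.3e-08, and adjusted p = 0.113 with an estimated correlation) had 10 of 15 members down, among them Il12rb2 (-2.89), and 1 up. T helper 2 genes (median -1.20, adjusted p = 4.82e-07, and adjusted p = 0.113 with an estimated correlation) had 8 of 10 down, including Ccr8 (-3.08), Il10 (-2.51), Il13 (-1.77) and the lineage regulator Gata3 (-1.50). T helper 17 genes (median -0.40, adjusted p = 0.000344, and adjusted p = 0.161 with an estimated correlation) had 7 of 9 down, including Il17a (-3.13) and Il17f (-2.54), while Rora rose (0.72). Regulatory T cell genes (median -1.55, adjusted p = 2.86e-12, and adjusted p = 0.122 with an estimated correlation) had 12 of 15 down, including Gpr83 (-3.49), the high-affinity interleukin 2 receptor chain Il2ra (-3.04) and the lineage regulator Foxp3 (-2.89). Genes of effector differentiation opposed to Bcl6 fell (median -0.64, adjusted p = 6.11e-05, and adjusted p = 0.144 with an estimated correlation), with 10 of 15 down, including Prdm1 (-2.12), the repressor that antagonises Bcl6, and 3 up. Naive and central memory genes fell (median -0.64, adjusted p = 0.00663, and adjusted p = 0.149 with an estimated correlation), with 7 of 12 down, led by Dapl1 (-2.04), Il7r (-1.58) and the survival gene Bcl2 (-1.31), and 3 up. That call ended among genes above the median level (adjusted p = 0.122).

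Signalling and cytokine lists fell in the same comparison. Of 19 measured cytokines, 16 fell, including Il3, Ifng and Csf2 (-2.86), and 1 rose (median -1.77, adjusted p = 7.71e-15, and adjusted p = 0.113 with an estimated correlation). Among type I interferon response genes 18 of 19 fell, including Ifit3 (-2.99), Ifit1 (-2.54) and Zbp1 (-1.87), with a median of -1.36 (adjusted p = 1.15e-15, and adjusted p = 0.0721 with an estimated correlation). T cell receptor early response genes, which follow antigen contact, fell in 14 of 15 cases, including Myc (-1.97), Irf4 (-1.55) and Nr4a1 (-1.32), with a median of -1.29 (adjusted p = 8.85e-13, and adjusted p = 0.122 with an estimated correlation). Cytokine receptors fell (median -0.61, adjusted p = 0.000498, and adjusted p = 0.233 with an estimated correlation), with 13 of 22 down, such as Il12rb1 (-2.05) and Il15ra (-2.03), and 5 up, and the call ended among genes above the median level (adjusted p = 0.0517). Chemokine receptors and trafficking genes moved both ways, with 8 up and 10 down of 24, including Ccr9 (-3.00) and Itgae (-2.38) (adjusted p = 0.43, and 0.184 without the sort gene Cxcr5, which this list holds). Coinhibitory receptors did so as well, with Havcr2 (-2.97) and Cd160 (-1.36) down and Tigit (1.15) and Pdcd1 (0.60), which encodes PD-1, up, among 2 rises and 5 falls of 10 (adjusted p = 0.123). With fry both lists passed downward (adjusted p = 0.00985 for trafficking and 0.00269 for coinhibitory receptors).

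Cell cycle genes rose (median 0.64, adjusted p = 4.6e-05, and adjusted p = 0.38 with an estimated correlation), with 19 of 29 up, such as Ccnb2 (1.14), Mki67 (1.12) and Mcm6 (0.92). The 5 that fell, 4 of them named after their values were seen, encode replication factors: Mcm2 (-0.86), Pcna (-0.57), Mcm3 (-0.44), Mcm5 (-0.39) and Mcm4 (-0.31). Glycolysis and mTORC1 genes fell (median -0.18, adjusted p = 0.0281, and adjusted p = 0.161 with an estimated correlation), with 7 of 15 down, including Hk2 (-1.64), Slc7a5 (-1.50) and Slc2a1 (-1.08), and 2 up. That call ended after quantile normalisation (median -0.11, adjusted p = 0.118), among genes above the median level (0.246) and without Cxcr5-Bcl6- replicate 1 (0.0623). Cholesterol synthesis genes were not called (3 up and 4 down of 14, adjusted p = 0.806). Their balance turned to 6 up and 2 down after quantile normalisation and to 4 up and 2 down with the replicate number as a term. Dissociation and stress genes fell (median -0.78, adjusted p = 1.28e-05, and adjusted p = 0.113 with an estimated correlation), with 11 of 15 down, led by Atf3 (-3.36) and Fos (-1.55), while Ddit4 rose (1.28). Ribosomal protein genes fell by a median of 0.12 on the log2 scale (adjusted p = 0.0141, and adjusted p = 0.38 with an estimated correlation), with 5 of 23 down, including Rpl12 (-1.55). That call ended among genes above the median level (adjusted p = 0.194), without Cxcr5-Bcl6- replicate 1 (0.0842) and without either Cxcr5+Bcl6- replicate (0.0527). T cell core genes were not called (5 up and 3 down of 13, adjusted p = 0.325), with Cd4 up by 0.79, though the list passed upward with fry (adjusted p = 0.0253).

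Markers of other cell types moved beside these groups. B cell genes were higher in Cxcr5+Bcl6+ cells (median 0.80, adjusted p = 0.000364, and adjusted p = 0.122 with an estimated correlation), with 9 of 14 up, including Fcer2a (2.43), Ms4a1 (1.89), Cd79b (1.61) and Cd79a (1.46), and 3 down. That call ended among genes above the median level (adjusted p = 0.236). Myeloid and dendritic cell genes were lower (adjusted p = 0.00379, and adjusted p = 0.149 with an estimated correlation), with a median of -0.05, which was -0.10 after quantile normalisation and -0.08 after centring, 12 of 26 down, including Mpeg1, Siglech (-2.88), Tyrobp (-2.46) and Cd209a (-2.02), and 3 up. CD8 T cell genes were lower (median -0.76, adjusted p = 8.94e-06, and adjusted p = 0.122 with an estimated correlation) in 8 of 9 cases, including Crtam (-2.34) and Cd8a (-1.20). NK and innate-like T cell genes were lower (median -0.50, adjusted p = 0.00258, and adjusted p = 0.161 with an estimated correlation), with 7 of 11 down, although Klrb1c rose (1.21). Germinal centre B and plasma cell genes were lower (median -0.19, adjusted p = 0.0369, and adjusted p = 0.161 with an estimated correlation), with 5 of 11 down, led by Prdm1, Irf4 and Xbp1 (-1.02), and 2 up, and the call ended among genes above the median level (adjusted p = 0.0952). Stromal and endothelial genes (2 up and 1 down of 13, adjusted p = 0.367) and erythroid and platelet genes (5 measured, all not past the threshold, adjusted p = 0.637) were not called.

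Small exceptions within these lists, named after their values were seen, were the rises of Stat4 (0.90) among T helper 1 genes, Il21 (0.54) among cytokines, S1pr1 (1.04), Lef1 (0.49) and Actn1 (0.37) among naive genes, and S1pr1, Rora and Zeb2 (0.33) among effector genes. Others were the rises of Hif1a (0.60) and Tpi1 (0.32) among glycolysis genes, of Lyz2 (1.096), Lyz1 (0.37) and C1qc (0.27) among myeloid genes, and of S1pr2 (0.74) and Mybl1 (0.30) among germinal centre genes. After quantile normalisation, and also after centring, the myeloid list had 2 rises and the germinal centre list 1. Among cytokine receptors the rises were Il6ra (0.92), Ifnar2 (0.73), Tgfbr2 (0.61), Il1r2 (0.52) and Ifnar1 (0.52), and among B cell genes the falls were Fcrla (-0.81), Ighm (-0.49) and Spib (-0.30).

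In total 8255 of 23410 probe sets passed, 4111 higher and 4144 lower in Cxcr5+Bcl6+ cells, and 345 rises and 856 falls were at least 2-fold. Rises made up 49.8% of calls, and 40.1% to 52.0% under the alternatives, with 51.6% after quantile normalisation and 45.3% after centring each array. Adjusted over the list alone, counts differed for follicular helper (18 up), T helper 1 (2 up), regulatory T cell (13 down), glycolysis (3 up), T cell receptor (15 down), trafficking (9 up) and ribosomal (4 down) genes, and were equal for the other lists. Among calls below the median level 74.2% were rises, against 41.1% above it, and 1207 olfactory, vomeronasal and trace-amine receptor genes, which T cells are not known to use, had a median change of 0.223 (SE 0.0069). This SE comes from the scatter between genes, which share the same arrays, and not between arrays. Of these receptor genes 419 passed as rises and 1 as a fall, so a rise called at low level is not by itself evidence of a change in T cells. Camera called 20 of 26 lists at the preset correlation and 0 with an estimated correlation, where 9 had an unadjusted p under 0.05, and fry called 23.

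**Figure D2:**
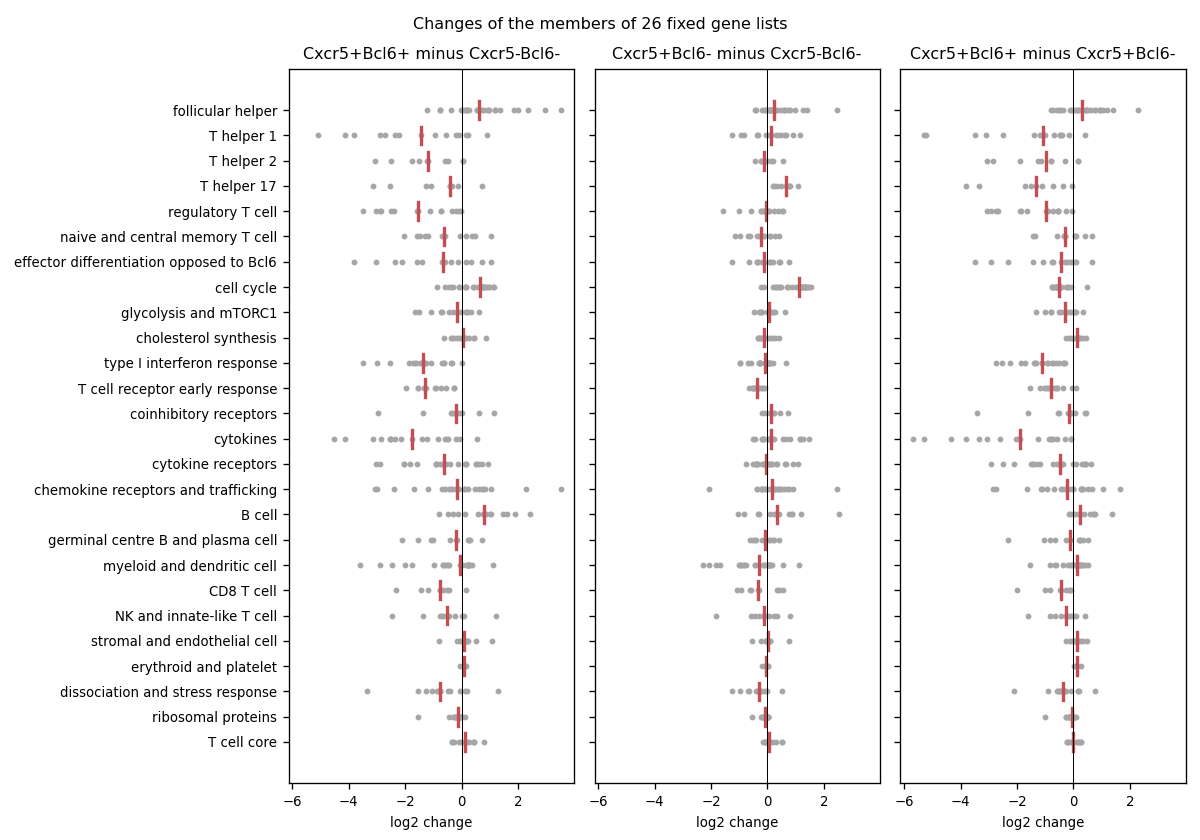
Log2 change (horizontal axis) of each measured member (grey dots) of the 26 lists, with the median of each list as a red line, for the 3 comparisons. The cytokine median was -1.77 for Cxcr5+Bcl6+ minus Cxcr5-Bcl6-, 0.12 for Cxcr5+Bcl6- minus Cxcr5-Bcl6- and -1.88 for Cxcr5+Bcl6+ minus Cxcr5+Bcl6-.

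Compared with Cxcr5-Bcl6- cells, Cxcr5+Bcl6- cells had higher levels of 24 of 29 cell cycle genes, 11 of 29 follicular helper genes and 7 of 19 cytokine genes, and lower levels of 13 of 26 myeloid and dendritic cell genes. Fcer2a (probe set 10576757), the low-affinity IgE receptor gene known from B cells, was 5.87-fold higher (9.39 ± 0.0534 against 6.84 ± 0.208, SD, n = 2 each). Hmmr (probe set 10385248), which encodes a spindle-associated hyaluronan receptor, was 3.21-fold higher (8.93 ± 0.118 against 7.24 ± 0.0278). Ccl22 (probe set 10574213), a chemokine gene expressed by mature dendritic cells, was 8.03-fold lower (8.37 ± 0.00476 against 11.37 ± 0.0656). Siglech (probe set 10553559), a marker of plasmacytoid dendritic cells, was 4.83-fold lower (8.11 ± 0.0019 against 10.38 ± 0.00971). Their adjusted p was 2.07e-07, 1.34e-06, 5.11e-08 and 5.42e-07.

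The other large rises were the phosphatase gene Cdc25b (1.59), the histone gene H2ac4 (1.57), Dnase1l3 (1.57), the mitotic genes Bub1 (1.55), Nusap1 (1.501) and Kif4 (1.48), and St6galnac1 (1.49). The other large falls were Apol7c (-2.69), the dendritic cell lectin gene Cd209d (-2.59), Pld4 (-2.27), the actin-bundling gene Fscn1 (-2.20), Ly6d (-2.16), Mpeg1 (-2.09), the chemokine receptor gene Ccr9 (-2.07) and Rnase6 (-2.05). Apol7c had the widest spread of these in Cxcr5-Bcl6- cells (SD 0.728). Each had an adjusted p of 3.07e-05 or less.

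Cell cycle genes rose in 24 of 29 cases, including Bub1, Cenpe (1.46), Mki67 (1.37) and Tpx2 (1.36), with a median of 1.099 (adjusted p = 2.68e-36, and adjusted p = 0.186 with an estimated correlation). Follicular helper genes rose (median 0.22, adjusted p = 1.05e-08, and adjusted p = 0.187 with an estimated correlation), with 11 of 29 up, including Sh2d1a (1.39), Il21 (1.27), the helper cytokine of germinal centres, and Slamf6 (0.97). Without the sort genes the median was 0.20 (adjusted p = 4.14e-07, and adjusted p = 0.211 with an estimated correlation). The 2 that fell, named after their values were seen, were Rgs16 (-0.40) and Il4 (-0.43), which did not pass without Cxcr5-Bcl6- replicate 1 (adjusted p = 0.0852) or without Cxcr5+Bcl6- replicate 2 (0.168). T helper 17 genes rose (median 0.67, adjusted p = 8.39e-10, and adjusted p = 0.186 with an estimated correlation), with 5 of 9 up, namely Il23r (1.09), Il17f (0.78), Ccr6 (0.78), Rora (0.77) and Il17a (0.67). Cytokines rose as a list (median 0.12, adjusted p = 0.000385, and adjusted p = 0.282 with an estimated correlation), with 7 of 19 up, including Csf2 (1.47), Ifng (1.17) and Il3 (1.15), and 2 down. Chemokine receptors and trafficking genes rose (median 0.17, adjusted p = 0.00276, and adjusted p = 0.187 with an estimated correlation), with 9 of 24 up, including Cxcr3 (0.91), and 3 down, led by Ccr9. The list holds Cxcr5, and without it the mean fell from 0.18 to 0.08 and the median to 0.13 (adjusted p = 0.0219, and adjusted p = 0.241 with an estimated correlation). Coinhibitory receptors rose (median 0.13, adjusted p = 0.0126, and adjusted p = 0.331 with an estimated correlation), with Tigit (0.74) and Havcr2 (0.44) the 2 of 10 past the threshold. Havcr2 did not pass without Cxcr5+Bcl6- replicate 1 (adjusted p = 0.0956).

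Lists that fell were led by T cell receptor early response genes (median -0.36, adjusted p = 3.57e-08, and adjusted p = 0.19 with an estimated correlation), with 9 of 15 down, including Dusp2 (-0.67), Cd69 (-0.54) and Irf4 (-0.52). Dissociation and stress genes fell (median -0.30, adjusted p = 1.12e-05, and adjusted p = 0.186 with an estimated correlation), with 7 of 15 down, including Atf3 (-1.25) and Jun (-0.99), and 1 up. Naive and central memory genes fell (median -0.22, adjusted p = 0.00889, and adjusted p = 0.19 with an estimated correlation), with 6 of 12 down, including Igfbp4 (-1.15), Bcl2 (-0.99) and Dapl1 (-0.68), and 1 up. Type I interferon response genes fell (median -0.10, adjusted p = 0.0236, and adjusted p = 0.19 with an estimated correlation), with 4 of 19 down, namely Oas2 (-0.98), Usp18 (-0.97), Bst2 (-0.70) and Oasl2 (-0.58), and 1 up. The median was -0.06 after quantile normalisation. That call ended without Cxcr5-Bcl6- replicate 1 (adjusted p = 0.0952).

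The remaining T cell lists were not called. T helper 1 genes had 6 up, including Ifng and Cxcr3, and 5 down, including Ccl5 (-1.27) and Eomes (-0.94), of 15 (adjusted p = 0.163). Regulatory T cell genes had 3 up and 3 down of 15, the latter Gpr83 (-1.59), Lrrc32 (-1.01) and Ikzf4 (-0.58) (adjusted p = 0.449). The T helper 2 list (1 up and 1 down of 10), the effector list (3 up and 5 down of 15), the glycolysis list (1 up and 2 down of 15) and the cholesterol list (1 up of 14) each had an adjusted p of 0.595. Cytokine receptors had 4 up and 7 down of 22 (adjusted p = 0.664), with a median of -0.05, which was -0.03 after quantile normalisation or centring, but a mean of 0.03 and a test direction upward. Ribosomal protein genes (1 down of 23, adjusted p = 0.163) and T cell core genes (2 up of 13, adjusted p = 0.0785), among them Cd4 (0.51), were not called, though the ribosomal list passed downward after quantile normalisation (adjusted p = 0.0329) and without Cxcr5-Bcl6- replicate 2 (0.0417).

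Among markers of other cells, myeloid and dendritic cell genes were lower in Cxcr5+Bcl6- cells (median -0.30, adjusted p = 2.44e-07, and adjusted p = 0.186 with an estimated correlation), with 13 of 26 down, including Siglech, Mpeg1, Tyrobp (-1.83) and Cd209a (-1.67), and 2 up. B cell genes were higher (median 0.32, adjusted p = 0.000344, and adjusted p = 0.187 with an estimated correlation), with 7 of 14 up, including Ms4a1 (1.18) and Ebf1 (0.76), and 3 down. That call ended among genes above the median level (adjusted p = 0.864). CD8 T cell genes were lower (median -0.35, adjusted p = 0.0219, and adjusted p = 0.282 with an estimated correlation), with 5 of 9 down, including Cd8a (-1.07) and Cd8b1 (-0.63), and 2 up, and that call ended without Cxcr5-Bcl6- replicate 1 (adjusted p = 0.149). NK and innate-like genes (1 up and 3 down of 11, adjusted p = 0.263), germinal centre B and plasma cell genes (1 up and 4 down of 11, adjusted p = 0.36), stromal genes (1 up and 1 down of 13, adjusted p = 0.77) and erythroid genes (5 measured, all not past the threshold, adjusted p = 0.731) were not called. The NK list passed downward with fry (adjusted p = 0.0458) and among genes above the median level (0.0457), and the germinal centre list with fry (0.025).

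Small exceptions in this comparison, named after their values were seen, were the rises of Mx1 (0.65) among interferon genes, S1pr1 (0.40) among naive genes, Ddit4 (0.52) among stress genes, Lyz2 (1.11) and Lyz1 (0.56) among myeloid genes, and Klrc1 (0.56) and Gzmk (0.42) among CD8 T cell genes. The exceptional falls were Lif (-0.51) and Il4 among cytokines, and Spib (-1.06), Fcrla (-0.81) and Ighm (-0.33) among B cell genes.

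In total 2610 probe sets passed, 1221 higher and 1389 lower in Cxcr5+Bcl6- cells, with 123 rises and 110 falls of at least 2-fold. The balance turned with the setting: rises made up 46.8% of calls, but 53.1% after quantile normalisation, 52.7% after centring each array, 51.4% among probe sets above the median level, 52.0% over all rows, 53.8% without Cxcr5-Bcl6- replicate 1 and 52.6% without Cxcr5+Bcl6- replicate 2. Adjusted over the list alone, counts differed for follicular helper (13 up), T helper 17 (8 up), regulatory T cell (4 down), naive (2 up), cell cycle (26 up, 1 down), cholesterol (2 up, 4 down), interferon (9 down), T cell receptor (11 down), cytokine receptor (6 up), trafficking (10 up), B cell (9 up, 4 down), CD8 (3 up, 6 down), NK (4 down) and stress (11 down) genes, and were equal for the other lists. The count was 1317 without Cxcr5+Bcl6- replicate 1, 1401 without replicate 2 and 1579 over all rows. Below the median level 26.5% of calls were rises, against 52.4% above it. The 1207 receptor genes had a median change of -0.0685 (SE 0.0042, from the scatter between genes), with 1 passing as a rise and 7 as falls. A small fall at low level is therefore not by itself evidence of a change in T cells. Camera called 13 of 26 lists at the preset correlation and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05, and fry called 15.

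Within the Cxcr5+ cells, those with Bcl6 had lower levels of 17 of 19 cytokine genes and higher levels of 15 of 29 follicular helper genes than those without. Whether the cells were restimulated before RNA extraction, on which cytokine levels would depend, is not given in the sources used here. Ifng was 39.6-fold lower (7.50 ± 0.00584 in Cxcr5+Bcl6+ against 12.81 ± 0.0149 in Cxcr5+Bcl6- cells, SD, n = 2 each). Il3 (probe set 10385918), a haematopoietic growth factor gene, was at least 51.0-fold lower (5.38 ± 0.0901 against 11.05 ± 0.0899), a lower bound because its level in Cxcr5+Bcl6+ cells lay under the median of 5.80 of the receptor genes. Csf2 (probe set 10385912), the gene of the growth factor GM-CSF, was 20.2-fold lower (7.25 ± 0.0984 against 11.59 ± 0.0683), and Il17a (probe set 10345032) 13.9-fold lower (8.56 ± 0.0407 against 12.37 ± 0.102). Padi4 (probe set 10517791) was 5.59-fold higher (9.85 ± 0.133 against 7.37 ± 0.115), and Cxcr4 (probe set 10357472), a chemokine receptor gene active in germinal centres, 3.16-fold higher (12.85 ± 0.0889 against 11.19 ± 0.0311). The adjusted p was 2.23e-11, 9.47e-11, 6.18e-10, 8.4e-10, 3.48e-08 and 2.48e-07.

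The other large falls were Gzmb (-5.22), Ccl3 (-4.65), Socs2 (-3.84), Iigp1 (-3.81), Tbx21 (-3.47) and Havcr2 (-3.41), which encodes the inhibitory receptor TIM-3. The other large rises were Sostdc1 (2.29), Dnase1l3 (2.19), Spock2 (1.74), the multi-copy Y-linked gene Srsy (1.44), Tubb2b (1.43), Nfia (1.42), Pde2a (1.41) and Hpgds (1.41). Each had an adjusted p of 3.4e-06 or less.

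Among follicular helper genes 15 of 29 rose, including Ascl2 (1.40), Tox2 (1.21) and the sort gene Bcl6, and 6 fell (median 0.30, adjusted p = 0.00178, and adjusted p = 0.238 with an estimated correlation). Without the sort genes the median was 0.20 (adjusted p = 0.0118, and adjusted p = 0.318 with an estimated correlation). The genes of other lineages fell. Among T helper 1 genes 13 of 15 fell, including Nkg7 (-3.08), and 1 rose (median -1.09, adjusted p = 1.83e-16, and adjusted p = 0.0679 with an estimated correlation). T helper 2 genes fell in 8 of 10 cases, including Il10 (-3.06) and Ccr8 (-2.84), with a median of -0.98 (adjusted p = 8.2e-09, and adjusted p = 0.0679 with an estimated correlation). T helper 17 genes fell in 8 of 9 cases, including Il17f (-3.33), Ccl20 (-1.73) and Il23r (-1.49), with a median of -1.31 (adjusted p = 1.31e-11, and adjusted p = 0.0906 with an estimated correlation). Regulatory T cell genes fell in 14 of 15 cases, including Il2ra (-2.92), Itgae (-2.75) and Foxp3 (-2.67), with a median of -0.97 (adjusted p = 4.72e-18, and adjusted p = 0.0906 with an estimated correlation). The effector list had 9 of 15 down, including Prdm1 (-2.33), and 1 up (median -0.45, adjusted p = 1.07e-07, and adjusted p = 0.0906 with an estimated correlation). The naive list had 7 of 12 down, including Il7r (-1.44), and 2 up (median -0.29, adjusted p = 0.0245, and adjusted p = 0.182 with an estimated correlation), and its call ended after quantile normalisation (adjusted p = 0.139) and among genes above the median level (0.341).

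All 19 type I interferon response genes fell, including Ifit3 (-2.73), Usp18 (-2.53) and Ifit1 (-2.24), with a median of -1.11 (adjusted p = 5.96e-22). This was the 1 list call that held with an estimated correlation (adjusted p = 0.0447). Cytokines fell in 17 of 19 cases (median -1.88, adjusted p = 1.21e-24, and adjusted p = 0.0679 with an estimated correlation). T cell receptor early response genes fell in 13 of 15 cases, including Myc (-1.54) and Nr4a3 (-1.19), with a median of -0.79 (adjusted p = 1.97e-12, and adjusted p = 0.103 with an estimated correlation). Cytokine receptors had 15 of 22 down, such as Il12rb2 (-2.51), and 5 up (median -0.48, adjusted p = 8e-08, and adjusted p = 0.133 with an estimated correlation). Coinhibitory receptors had 4 of 10 down, including Cd160 (-1.60) and Ctla4 (-0.54), and 2 up, with Pdcd1 at 0.46 (median -0.14, adjusted p = 0.00925, and adjusted p = 0.233 with an estimated correlation), and the call ended among genes above the median level (adjusted p = 0.124). Chemokine receptors and trafficking genes had 10 of 24 down, including Ccr2 (-1.64), and 6 up (median -0.23, adjusted p = 0.00928, and adjusted p = 0.142 with an estimated correlation). That call ended after quantile normalisation (adjusted p = 0.0566) and among genes above the median level (0.844), and held without the sort gene Cxcr5 (0.00226).

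Cell cycle genes fell in 24 of 29 cases, including Tyms (-0.76), Mcm3 (-0.76) and Aurka (-0.59), with a median of -0.52 (adjusted p = 6.25e-14, and adjusted p = 0.169 with an estimated correlation). Glycolysis and mTORC1 genes had 8 of 15 down, including Hk2 (-1.33) and Slc7a5 (-1.02), and 1 up (median -0.29, adjusted p = 0.000217, and adjusted p = 0.0906 with an estimated correlation). Dissociation and stress genes had 10 of 15 down, led by Atf3 (-2.11), while Ddit4 rose (0.76) (median -0.37, adjusted p = 0.000669, and adjusted p = 0.0906 with an estimated correlation), and the call ended among genes above the median level (adjusted p = 0.0641). Cholesterol genes (2 up of 14, adjusted p = 0.278) and ribosomal protein genes (1 down of 23, adjusted p = 0.0646) were not called. The cholesterol list passed upward after quantile normalisation (adjusted p = 0.0142), and the ribosomal list passed downward with fry (0.039) and without Cxcr5+Bcl6+ replicate 1 (0.0496). T cell core genes had 1 up of 13 (adjusted p = 0.981), with a median of -0.03, which was 0.03 after quantile normalisation and -0.08 after centring, and a mean of 0.03 with a test direction upward.

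Among markers of other cells, B cell genes were higher in Cxcr5+Bcl6+ than in Cxcr5+Bcl6- cells in 6 of 14 cases, including Cd79b (1.38), Spib (0.76) and Cd22 (0.74), with a median of 0.24, which was 0.13 after quantile normalisation (adjusted p = 0.00315, and adjusted p = 0.133 with an estimated correlation), and the call ended among genes above the median level (adjusted p = 0.0641). CD8 T cell genes were lower in 5 of 9 cases, including Crtam (-1.99) and Klrc1 (-1.02), with a median of -0.45 (adjusted p = 2.18e-05, and adjusted p = 0.0973 with an estimated correlation). NK and innate-like genes had 5 of 11 down and 1 up (median -0.26, adjusted p = 0.00647, and adjusted p = 0.186 with an estimated correlation). Myeloid and dendritic cell genes had 4 up, including H2-Ab1 (0.52), and 5 down, including Mpeg1 (-1.54), of 26 (adjusted p = 0.981), with a median of 0.14, which was 0.01 after quantile normalisation and 0.09 after centring, but a mean of -0.03 and a test direction downward. Germinal centre B and plasma cell genes (2 up and 4 down of 11, adjusted p = 0.0677), stromal genes (2 up of 13, adjusted p = 0.278) and erythroid genes (5 measured, all not past the threshold, adjusted p = 0.367) were not called. The germinal centre list passed downward with fry (adjusted p = 0.00112), among genes above the median level (0.0424) and without Cxcr5+Bcl6- replicate 1 (0.0233) or 2 (0.0176), and the stromal list passed upward among genes above the median level (0.046).

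Small exceptions in this comparison, named after their values were seen unless already given, were the rises of Stat4 (0.43) among T helper 1 genes, S1pr1 (0.65) among effector genes, S1pr1 and Lef1 (0.41) among naive genes, Mcm6 (0.50) among cell cycle genes, Hif1a (0.35) among glycolysis genes and Tigit (0.41) beside Pdcd1 among coinhibitory receptors. The falls among follicular helper genes were Il4 (-0.80), Il21 (-0.72), Cd40lg (-0.57), Cd200 (-0.50), Batf (-0.47) and Rgs16 (-0.37).

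In total 6185 probe sets passed, 3144 higher and 3041 lower in Cxcr5+Bcl6+ cells, with 231 rises and 386 falls of at least 2-fold. Rises made up 50.8% of calls, but 49.1% after quantile normalisation, 39.6% after centring each array and 34.2% among probe sets above the median level, and up to 54.2% when single arrays were left out. Below the median level 86.3% of calls were rises, and the 1207 receptor genes had a median change of 0.299 (SE 0.0069). Of these receptor genes 567 passed as rises and 0 as falls, so the same limit holds for rises called at low level here. Adjusted over the list alone, counts differed for follicular helper (16 up), effector (10 down), cell cycle (25 down), glycolysis (9 down), trafficking (8 up, 13 down), B cell (8 up), germinal centre (3 up, 5 down) and T cell core (none past the threshold) genes, and were equal for the other lists. The count was 3617 without Cxcr5+Bcl6- replicate 1 and 3820 without replicate 2. Camera called 19 of 26 lists at the preset correlation and 1 with an estimated correlation, and fry called 21.

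**Figure D3:**
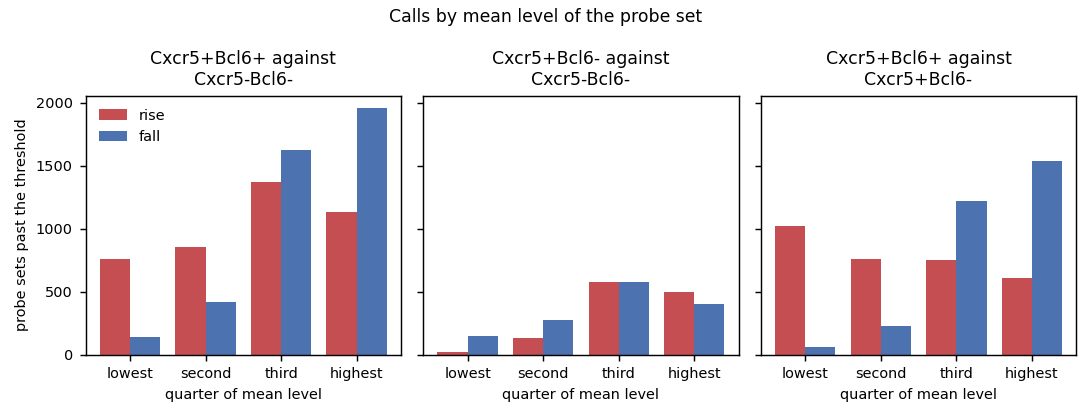
Probe sets past the threshold (vertical axis) in 4 classes of mean level with equal numbers of probe sets (horizontal axis), with rises and falls as separate bars, for the 3 comparisons. In the lowest class there were 761 rises and 141 falls for Cxcr5+Bcl6+ against Cxcr5-Bcl6-, 19 and 145 for Cxcr5+Bcl6- against Cxcr5-Bcl6-, and 1024 and 56 for Cxcr5+Bcl6+ against Cxcr5+Bcl6-.

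Both Cxcr5+ groups were compared with the same Cxcr5-Bcl6- arrays. Against these, 1003 probe sets rose in both groups and 1122 fell in both, where independent calls would give 214 and 246. In 100 simulations of unchanged groups with shared controls, 0.05 probe sets on average passed the same way in both. With no group changed, few calls could arise at all. That mean therefore does not show how much overlap shared controls add among genes that change. The 2 changes correlated at 0.612 across probe sets, which are not independent replicates, and simulated unchanged groups gave 0.5. Their covariance was 0.0738 against a simulated 0.00526. With the controls split, a check chosen after seeing the data that gave each comparison 1 of the 2 control arrays, 1477 or 1676 probe sets passed the same way in both, depending on which array went to which. Each fit then had a single control array, which was assumed to vary like the other groups, so the spread came from those groups alone. Independent calls would give 206 rises and 170 falls for the former, where 791 and 686 were found, and 123 and 182 for the latter, where 684 and 992 were found. The changes then correlated at 0.423 and 0.602. The total of 2125 was 1107 without Cxcr5+Bcl6- replicate 1 and 1158 without replicate 2. In opposite directions, 67 probe sets rose in Cxcr5+Bcl6- and fell in Cxcr5+Bcl6+ cells, and 144 did the reverse, of which 120 carried several symbols and 19 belonged to Srsy.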

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

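Among the tests in this part, the ratios of median changes that concern the interferon difference, with their bounds, were chosen after the result was seen, and so was the condition that a value must pass its bound by more than its spread, which was added after the B cell values were known, and the demand that the rise of the receptor genes end once all arrays have the same range. The other bounds were set before the values they judge. Each SE in this part comes from the scatter between genes, which share the same arrays, and not between arrays. A value that passes its bound by this spread is therefore not shown to recur in other arrays.

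The 2 Cxcr5+ groups moved past the threshold in opposite directions against Cxcr5-Bcl6- cells for 61 genes, with the difference between the groups itself past the threshold. Of these, 56 rose in Cxcr5+Bcl6- and fell in Cxcr5+Bcl6+ cells, and 5 did the reverse. The differences between the groups (log2, Cxcr5+Bcl6+ minus Cxcr5+Bcl6-, n = 2 each) included Ifng at -5.31, Csf2 at -4.33, Il17a at -3.80, Havcr2 at -3.41 and Il17f at -3.33. Il3, at -5.67, is a lower bound on the fall, because its level of 5.38 in Cxcr5+Bcl6+ cells lay under the median of 5.80 of the receptor genes weighed below. In data with no gene name, 2426 of 12146 probe sets passed between Cxcr5+Bcl6+ and Cxcr5-Bcl6- cells, 1357 higher and 1069 lower, with 266 and 287 of them changed at least 2-fold. The genes behind these probe sets are unnamed here.

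Rises outnumbered falls among dim probe sets in the Cxcr5+Bcl6+ arrays, at 74.2% of calls below the median level. A narrower signal range on these arrays cannot be told apart from other causes: the 1207 olfactory, vomeronasal and trace-amine receptor genes, themselves dim at a median level of 5.80, had a median change of 0.223 (SE 0.0069), which passes the bound set in advance. Renewed quantile normalisation, which gives all arrays the same range, still left them at 0.166 (SE 0.0066), though it can itself lift dim probe sets where many bright ones fall. The authors' scaling cannot be told apart from other causes either, because the share of rises was then 59.9%, between the bounds of 55% and 65%. A biological difference between the sorted groups stays open and was not tested.

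Dendritic cell genes were higher in the Cxcr5-Bcl6- arrays, and RNA of dendritic cells in that sort may be a source, because a gate on CD4 and CD44 would not remove dendritic cells that bear both. Further plasmacytoid markers had a median change of -0.837 (SE 0.189) in Cxcr5+Bcl6- against Cxcr5-Bcl6- cells, with 11 of 14 lower, 7 of the 14 being above level 9. The abundant Irf8 stood at 11.62, 10.97 and 8.88 in Cxcr5-Bcl6-, Cxcr5+Bcl6- and Cxcr5+Bcl6+ cells and Tcf4 at 10.13, 8.93 and 8.54. Pacsin1 (10.19, 10.11 and 9.795) and Ptprs (10.04, 10.01 and 9.30), also abundant, did not pass between Cxcr5+Bcl6- and Cxcr5-Bcl6- cells. For activated conventional dendritic cells the matching median of -0.131 (SE 0.216, 1 up and 4 down of 10, 5 above level 9) lay between its bounds. The 4 that fell were Cd80 (-1.20), Cd86 (-1.13), Cd40 (-0.94) and Ccl17 (-0.825), and Tbc1d4 rose (0.46). Cd83 stood at 11.73, 11.67 and 11.77 in the same order of groups and Cd40 at 9.99, 9.04 and 8.62. With members so divided, the median does not decide on this source. For the interferon difference, the interferon list changed by -0.0999 in Cxcr5+Bcl6- and -1.36 in Cxcr5+Bcl6+ cells, a ratio of 0.0735 (SE 0.0614), where all 14 plasmacytoid markers gave 0.968 (SE 0.327), but after quantile normalisation the ratios were 0.0465 (SE 0.0609) and 1.01 (SE 0.397), the latter above the bound of 0.25 by less than 2 SE. With the deposited values and after centring (0.912, SE 0.306), the plasmacytoid ratio lay above the bound by more than 2 SE. The SE of a ratio took its 2 medians as independent, although they share genes and control arrays. By that bound, required under each scaling, the ratios did not decide on plasmacytoid RNA. Between the Cxcr5+ groups, a comparison not fixed in advance for this question, the plasmacytoid markers had a median change of -0.0462 (SE 0.153, 3 up and 5 down of 14). The 5 that fell included Irf8 (-2.09) and Tlr7 (-1.46), and the 3 that rose included Ctsl (0.73). All 19 interferon genes fell between these groups, with a median of -1.11. These values argue against plasmacytoid RNA as the main source of the interferon difference between the Cxcr5+ groups. Against Cxcr5-Bcl6- cells, 12 of the 14 markers were lower in Cxcr5+Bcl6+ cells (median -0.864), so for that difference this source was not decided. The conventional markers gave a ratio of 0.156 (SE 0.271), so RNA of those cells cannot be told apart from other sources of the interferon difference. A difference in the T cells themselves stays open and was not tested.

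B cell genes were higher in both Cxcr5+ groups, and RNA of B cells is a possible explanation that the further B cell markers did not decide. Their median change was 0.134 (SE 0.173) in Cxcr5+Bcl6+ cells, with 6 up and 4 down of 14, 5 of the 14 being above level 9. In Cxcr5+Bcl6- cells it was -0.000992 (SE 0.127), with 1 up and 4 down. That value lies below the bound of 0.05 set in advance, but by less than its spread, so B cell RNA cannot be told apart from its absence in either group. The abundant Cd37 stood at 11.62, 11.85 and 11.98 in Cxcr5-Bcl6-, Cxcr5+Bcl6- and Cxcr5+Bcl6+ cells and Pou2f2 at 10.09, 10.24 and 10.62. Also above level 9 were Ralgps2 (9.20, 9.19 and 9.54), H2-Eb1 (10.46, 9.49 and 9.82) and Cd24a (9.95, 9.36 and 8.70). The dimmer Ly86 stood at 9.30, 8.33 and 8.08. Whether members shared with dendritic cells, which differed above, lowered the medians was not tested. A gate on CD4 would remove most B cells, while expression by the T cells themselves stays open.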

How the results depend on the processing

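Of the alternative values for named genes, 3323 kept direction and side of the threshold, 35 passed it anew, 68 no longer passed and 6 changed sign. For lists the numbers were 912, 16, 72 and 11. The cause was not tested unless given. With a change of at least 1.5-fold required, 3470, 822 and 1952 probe sets remained for Cxcr5+Bcl6+ against Cxcr5-Bcl6-, Cxcr5+Bcl6- against Cxcr5-Bcl6- and Cxcr5+Bcl6+ against Cxcr5+Bcl6-, by construction. All rows gave 1579 for the second of these. An estimated correlation left camera with 0, 0 and 1 lists, with 9, 6 and 11 at an unadjusted p under 0.05. With fry, 23, 15 and 21 were called. With an estimated correlation, camera uses only the 3 residual degrees of freedom of the fit. Calls also ended in lists whose estimate lay below the preset 0.01, though other lists had higher estimates. For interferon genes in the first comparison the estimate was -0.0339, yet the unadjusted camera p went from 4.42e-17 to 0.00277. Higher correlation does not account for such losses. Levels near background limit what dim probe sets can show, and detection calls are not given in the sources used here.

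With single arrays left out, fewer samples remained and the lone array of a group was assumed to vary like the other groups. Counts then ranged from 6780 to 8370, from 1317 to 2624 and from 3617 to 6987, with 18 to 20, 11 to 14 and 19 to 20 lists, and the overlap from 1107 to 2057. The lowest values came without Cxcr5-Bcl6- replicate 1 for the first count, and without Cxcr5+Bcl6- replicate 1 for the others and the overlap. Without Cxcr5+Bcl6- replicate 2 these were 1401, 3820 and 1158.

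Lists that changed direction were past the threshold under neither setting. They were, by adjusted p, trafficking (0.311) for Cxcr5+Bcl6+ against Cxcr5-Bcl6- and myeloid genes (0.768) for Cxcr5+Bcl6+ against Cxcr5+Bcl6-, both above the median level, and T cell core (0.998) in the latter after centring. With arrays left out, adjusted p ranged for cholesterol from 0.517 to 0.859 and erythroid from 0.348 to 0.989 (Cxcr5+Bcl6+ against Cxcr5-Bcl6-), cholesterol from 0.281 to 0.984 and stromal from 0.298 to 0.816 (Cxcr5+Bcl6- against Cxcr5-Bcl6-), and myeloid from 0.688 to 0.985 and T cell core from 0.681 to 0.984 (Cxcr5+Bcl6+ against Cxcr5+Bcl6-). Likewise log2 changes ranged for Ppbp from -0.009294 to 0.16 and Gp9 from -0.09507 to 0.2205 in the first comparison, Alas2 from -0.02092 to 0.08527 in the second and Gp9 from -0.01342 to 0.3022 in the third.

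Replicate numbers are shared between groups, but deviations from group means correlated at -0.234, 0.258 and -0.0461, so they were not taken to pair the arrays. A replicate block gave 7942, 2411 and 5862 probe sets, 20, 13 and 19 lists and an overlap of 1958.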

Other observations

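Further single genes from the 61 that moved in opposite directions are given here. They were chosen after their values were seen, from genes selected for that pattern, so they are no test of any gene group, and they were not refitted without single arrays. Iltifb, a homologue of the interleukin 22 gene, changed by 1.34 and -1.60 (log2, Cxcr5+Bcl6- and Cxcr5+Bcl6+ each against Cxcr5-Bcl6-, n = 2 each), and the chemokine gene Ccl1 by 0.72 and -2.33. The interleukin 1 receptor antagonist gene Il1rn changed by 0.60 and -0.70, the protease inhibitor gene Timp1 by 0.70 and -0.53, and the interleukin 18 receptor chain gene Il18rap by 0.65 and -0.54. The protease gene Furin changed by 0.50 and -1.24, and the antiviral membrane genes Ifitm1 by 0.43 and -0.55 and Ifitm2 by 0.45 and -0.76. The differences between the Cxcr5+ groups were -2.94 for Iltifb, -3.05 for Ccl1 and -1.74 for Furin (adjusted p = 2.72e-09, 2.39e-09 and 2.13e-07). In the opposite sense, Rgs2, a regulator of G protein signals, changed by -0.45 and 0.42.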
